A study of Mus musculus with 46 samples.

How the data were processed

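RNA was sequenced from mice carrying a biotin-taggable Mecp2 allele, with the tag on either the wild-type protein (WT) or the Rett syndrome missense forms R106W and T158M. Cre recombinase drove BirA biotin ligase in a chosen cell class, so that nuclei with biotinylated MeCP2 could be sorted with streptavidin, an antibody to the neuronal protein NeuN and the DNA stain DAPI. The 46 libraries fell into 17 groups. Male excitatory and male inhibitory cortical nuclei at 6 weeks had 4 libraries for each of WT, R106W and T158M, each from 2 to 3 pooled mice. Female excitatory nuclei at 18 weeks, 1 mouse per replicate, had 2 libraries for each of 5 groups: WT/WT females, and the WT-expressing and mutant-expressing nuclei of R106W and of T158M heterozygotes. Unsorted male cortex at 6 weeks had 2 libraries per genotype (WT and R106W) for whole-cell RNA, nuclear RNA and global run-on sequencing (GRO-seq), which captures RNA being made by engaged polymerases. The labels do not say whether the cortex replicates were separate animals, so a p-value there measures only the spread between samples. Male libraries at 12 weeks, which the protocol names, were not analysed here.

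The deposited files hold raw counts per gene, one table per library, with 37349 Ensembl genes and their positions in the mouse genome build mm10. The submitters' notes name CASAVA 1.8, STAR 2.3.0, edgeR and DESeq2. They state neither the counting program, nor its strand setting, nor whether intron reads were counted, so a count is taken here as reads assigned to a gene by rules not given. Library totals ran from 18.6 to 193.7 M counts (M, mega), with a median of 32.2 M. The highest total belonged to nuclear RNA WT replicate 2, and the next was 64.2 M. Across the 47 pairs of libraries within a group, counts differed by 3.99 to 49.7 times the variance of random sampling (chi-square per degree of freedom). This is an average over genes with at least 20 counts in a pair. The spread between replicates thus exceeded counting error on average, which does not show the same for genes with few counts.

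Counts were analysed in R 4.3.3 with edgeR 4.0.16: low counts were removed with filterByExpr, libraries scaled with TMM, and groups compared with the quasi-likelihood F-test in a model with 1 mean per group and no covariate. Separate fits served the 12 male excitatory libraries, the 12 male inhibitory libraries, the 24 male sorted libraries together (for the difference between cell classes and for the difference of mutant effects between them), the 10 female libraries, and each cortex assay. A fit of the 12 cortex libraries tested whether the R106W effect differed between assays. These gave 21 comparisons. Within each, p-values were adjusted over all tested genes by the Benjamini-Hochberg method, and an adjusted p under 0.05 without a fold limit counted as called. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of F. Group levels are means of TMM-normalised counts per M (CPM) with their standard deviation (SD).

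Gene groups were tested with camera from limma 3.58.1, two-sided, with its preset correlation of 0.01 and again with the correlation estimated from the residuals, adjusted over the lists within a comparison. The 21 fixed lists were markers of excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, and endothelial and mural cells; immediate early genes; genes linked to MeCP2 in earlier literature; glucocorticoid-responsive genes; neuropeptides; voltage-gated potassium channels; voltage-gated sodium and calcium channels; glutamate receptors; GABA receptors; synaptic adhesion and axon guidance genes; nuclear-encoded respiratory chain and ATP synthase genes; cytosolic ribosomal proteins; DNA methylation readers, writers, erasers and the NCoR/SMRT complex; nuclear-retained long noncoding RNAs; and mitochondrially encoded genes, of which the files hold 0 of 15. A further 2 sets followed a rule: genes spanning over 100 kb, and genes on chromosome X within 5 Mb of Mecp2. The long-gene shift is the median log2 fold change of the genes over 100 kb minus that of the other tested genes. It was computed for 9 comparisons.

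The comparisons, tests, lists and alternatives, and the rule for naming genes, were fixed before the data were examined. For each of 13 main comparisons (R106W and T158M against WT in each male cell class, the 2 differences of effects between classes, mutant against WT nuclei and WT nuclei against WT/WT in each heterozygote, and the 3 cortex assays) the rule took, among called genes with a mean of at least 1 CPM in the higher group and every library of 1 group above every library of the other, the 8 largest rises and the 8 largest falls. It added the list members with the smallest p-values and left out predicted models, clones and small RNAs. For the differences of effects no separation of libraries was asked for. The text says where a gene outside the rule was chosen after its values were seen.

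Same-numbered libraries of 2 groups were treated as paired where there were at least 3 pairs and the residuals of every pair correlated above 0.1. This held for WT with R106W (0.12 to 0.40) and WT with T158M (0.15 to 0.72) in male excitatory nuclei. The value with replicate number as a block is then given beside the result. WT and mutant nuclei of a heterozygote were treated as paired too, because the protocol gives a single mouse per replicate; it does not say outright that equal numbers mark the same mouse, but the residuals correlated at 0.79. For the other groups the labels do not say that a number marks a shared animal, litter or day. The alternatives tried were DESeq2 1.42.0, its median-ratio (RLE) size factors in edgeR, no filter on low counts, only the 8 libraries of the 2 compared groups, replicate number as a block, 1 fit over the 12 cortex libraries, leaving out each library in turn, a limit of 200 kb for long genes, Spearman's rho with log10 gene length, fry, and camera with an estimated correlation. Added after seeing the data were crossed replicate numbers as a block, for nuclear RNA, replicate number across genotypes as a block, for heterozygotes against WT/WT females, and replicate number among the excitatory libraries as a block, for differences of effects between cell classes. A leave-one-out fit that left 1 library in a group assumed that it varied like the other groups. The pipeline was tested on simulated data in which 200 genes were changed by 1.5-fold, 2-fold or 3-fold: for male excitatory nuclei it called 70.1% of the genes changed 1.5-fold and 97.0% of those changed 2-fold, with false calls making up 6.35% of the calls.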

Results

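Gene counts were compared in 46 mouse cortex libraries: 24 of nuclei sorted from males, 10 of nuclei sorted from females, and 12 of unsorted male cortex. Each male sorted group had 4 libraries and every other group had 2. Total counts per library ran from 18.6 to 64.2 M, apart from nuclear RNA WT replicate 2 with 193.7 M. Mecp2 itself was present in every group, as missense alleles would leave it, at 94.6 to 113 CPM in the sorted nuclei. In what follows "rose" and "fell" are used of genes called by edgeR quasi-likelihood with a Benjamini-Hochberg adjusted p under 0.05, over 21 comparisons that were adjusted separately. Fold changes are log2.

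The sorted populations carried the transcripts of their class. Of 22 inhibitory neuron markers tested in WT males, 21 rose in inhibitory against excitatory nuclei and 1 fell, with a median difference of 6.08. Gad1, which makes GABA, stood at 394 to 484 CPM in the 4 inhibitory libraries and at 3.94 to 7.11 CPM in the 4 excitatory ones. Among 19 excitatory markers 15 fell, 2 rose and 2 did not pass (median −2.76). Slc17a7, the vesicular glutamate transporter, stood at 17.2 to 22.4 CPM in inhibitory and 102 to 136 CPM in excitatory nuclei. Neuropeptides rose in 14 of 16 cases (median 5.10), and of 21 genes linked to MeCP2 in earlier literature 12 rose and 6 fell. These 4 lists kept their camera call with an estimated correlation (adjusted p = 6.9e-05 for inhibitory markers, 9.1e-04 for excitatory markers, 0.0014 for neuropeptides and 0.0056 for the MeCP2-linked list). Other lists held many called genes but lost or lacked a call: 65 of 72 respiratory chain genes rose (adjusted p = 5.6e-06, and 0.416 with an estimated correlation), 13 of 17 immediate early genes fell (0.021, and 0.778 with an estimated correlation). Of 16713 genes tested, 5247 were higher in inhibitory and 4576 in excitatory nuclei, and adjusting over the list alone gave the same counts, 21, 15, 14 and 12, in the leading direction of these 4 lists.

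In male excitatory nuclei, R106W against WT asks what loss of methyl-DNA binding by this allele does to the main projection class. Tnc, the matrix glycoprotein tenascin C, fell by 2.32 (SE 0.30, adjusted p = 0.0021), from 1.93 ± 0.52 to 0.391 ± 0.14 CPM (SD, n = 4). Pappa2, a protease of insulin-like growth factor binding proteins, fell by 1.34 (SE 0.20, adjusted p = 0.0066). Armc4, a factor in assembling ciliary dynein arms, rose by 0.93 (SE 0.11, adjusted p = 0.0021), from 4.50 ± 0.50 to 8.58 ± 1.2 CPM. Further rises included Eya4, a transcriptional coactivator and phosphatase (0.97), the tyrosine kinase Tec (1.05), the secreted Wnt antagonist Sfrp1 (1.15) and Vstm4 (1.20), and also Rin3 (0.94), Crybg3 (0.86) and Gpr1 (0.85). Further falls were the hair-cell channel component Tmc1 (−1.49), the retinoic acid synthesis enzyme Aldh1a3 (−1.30), the acetylcholinesterase anchor Colq (−1.22), Itgbl1 (−1.15), the olfactory receptor Olfr78 (−1.12) and the chloride channel relative Ttyh2 (−1.10). Armc4, Pappa2 and Tnc, 3 of the 21 genes named for this comparison, were called under every alternative tried.

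Ion channel and receptor genes of the R106W excitatory nuclei lay mostly below WT. Of 26 voltage-gated sodium and calcium channel genes 2 fell and 24 did not pass: the T-type calcium channel Cacna1g (−0.69, SE 0.11, adjusted p = 0.011) and the sodium channel subunit Scn3b (−0.38, SE 0.071, adjusted p = 0.024); 6 fell when adjusted over the list alone. Among 29 potassium channel genes Kcnab1 fell (−0.43, adjusted p = 0.049), with 4 adjusted over the list alone. None of 23 glutamate receptor genes passed, although 20 lay below 0 and 2 passed adjusted over the list alone; Grik5 stood at −0.37 (SE 0.10) and Grin3a at −0.40 (SE 0.11). None of 14 GABA receptor genes passed either (3 adjusted over the list alone), with Gabra3 at −0.27. Camera called the sodium and calcium channels (median −0.11, adjusted p = 9.5e-05), glutamate receptors (median −0.17, 6.6e-05), potassium channels (0.010) and GABA receptors (0.030); with an estimated correlation the adjusted p was 0.0595 for the first and 0.655 for the other lists. Upward shifts were called for respiratory chain genes (median 0.085, 63 of 72 above 0, adjusted p = 0.0011, and 0.655 with an estimated correlation), ribosomal proteins (median 0.11, 0.0033, and 0.761 with an estimated correlation) and immediate early genes (median 0.18, 0.013, and 0.761 with an estimated correlation), in none of which a member passed. The upper-layer regulator Rorb rose (0.43, adjusted p = 0.034) and the presynaptic adhesion gene Nrxn2 fell (−0.47, adjusted p = 0.035).

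Of 15511 genes tested in R106W against WT excitatory nuclei, 82 rose and 91 fell. Same-numbered WT and R106W libraries were taken as paired because their residuals correlated, and with replicate as a block 653 genes were called. DESeq2 called 475, no filter on low counts 405, and only the 8 libraries of the 2 groups 36. The count was 24, 21, 363 and 374 without R106W replicates 1 to 4 in turn, and 59, 27, 32 and 68 without WT replicates 1 to 4.

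T158M, a second missense allele in the methyl-DNA binding domain, gave fewer calls in excitatory nuclei. Scn7a, an atypical sodium channel, fell to 0.419 of its WT level (log2 SE 0.15, adjusted p = 0.0023), from 5.02 ± 0.43 to 2.10 ± 0.26 CPM (SD, n = 4). Pappa2 fell by 1.24 (adjusted p = 0.0098), the growth factor binding protein Igfbp2 by 1.29, Olfr78 by 1.29, the neurexin-family gene Cntnap5c by 0.95 (from 59.4 to 30.8 CPM), Itgbl1 by 0.95, Zbbx by 0.90 and the lectin Clec18a by 0.86. Rises were led by Ranbp3l (0.94), the lipase Lipg (0.86, SE 0.12, adjusted p = 0.0076), the myeloid transcription factor Irf8 (0.86) and the collagen chain Col6a2 (0.85). They went on with the centrosomal gene Ccdc141 (0.77), Steap2 (0.76), the chemokine receptor Ackr3 (0.69) and the zinc-finger regulator Tshz1 (0.60, SE 0.085, from 30.7 to 46.3 CPM). Ccdc141, Lipg, Pappa2, Scn7a, Tshz1 and Zbbx, 6 of the 17 genes named, were called under every alternative.

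All 17 immediate early genes, the rapid transcriptional targets of neuronal activity, lay above WT in T158M excitatory nuclei. Their median was 0.47, none passed over all genes, and 6 passed adjusted over the list alone; Fos stood at 0.64 (SE 0.18), Arc at 0.60 (SE 0.19) and Egr1 at 0.45 (SE 0.11). Of 14 GABA receptor genes 13 lay below 0 (median −0.12) and 3 passed adjusted over the list alone, among them Gabra3 at −0.30 and Gabra5 at −0.35. Scn3b fell again (−0.39, adjusted p = 0.026). Camera called the immediate early genes (adjusted p = 8.3e-10), GABA receptors (7.5e-05), ribosomal proteins (2.0e-04), respiratory chain genes (2.6e-04) and glutamate receptors (0.0037, 1 member passing adjusted over the list alone). All of these had an adjusted p of 0.521 with an estimated correlation.

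Of 15511 genes tested in T158M against WT excitatory nuclei, 15 rose and 26 fell. Libraries were taken as paired here too, and with replicate as a block 112 genes were called. DESeq2 called 160 and no filter 114. The count was 18, 11, 18 and 18 without T158M replicates 1 to 4, and 20, 14 and 17 without WT replicates 1 to 3.

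Set against each other in excitatory nuclei, the 2 alleles differed at 2 genes, both lower in R106W and both named after their values were seen: Ccdc141 (−0.89, SE 0.11, adjusted p = 0.0061) and the pseudogene Gm11847 (−3.65). Of the genes called against WT, 6 rose and 16 fell with both alleles, where independence would give 0.079 and 0.15, and none went opposite ways. In R106W, 171 of its 173 called genes had the same sign in T158M. Both contrasts use the same 4 WT libraries, which by themselves make effects alike: across genes, which are not independent replicates, the log2 fold changes correlated at 0.518, and simulations with no effect and shared controls gave 0.506. The simulations drew each library independently, while these WT libraries were treated as paired with each allele, so 0.506 is not an exact reference. Splitting the WT libraries, so that each allele had its own 2 controls, gave a correlation of 0.139 and on average 0.50 genes higher and 0.67 lower with both alleles. Having 2 controls instead of 4 by itself lowers the correlation and the number of calls. The smaller overlap therefore cannot be credited to the end of sharing. The covariance across genes was 0.0268, against 0.0162 in the simulations and 0.0094 with the WT libraries split. Immediate early genes were lower in R106W than T158M by camera (median −0.22, adjusted p = 0.019, and 0.891 with an estimated correlation), as were sodium and calcium channels (0.019, and 0.284 with an estimated correlation) and nuclear-retained noncoding RNAs (median −0.20, 0.019, and 0.577 with an estimated correlation), with 1, 0 and 1 members passing adjusted over the list alone. DESeq2 called 58 genes and no filter 89. The count was 10 and 174 without R106W replicates 3 and 4, 1 without R106W replicate 2, and 2 or 3 otherwise.

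In male inhibitory nuclei with R106W, Gfra1, the co-receptor for glial cell line-derived neurotrophic factor, rose by 0.98 (SE 0.11, adjusted p = 0.0013), from 49.0 ± 6.7 to 96.6 ± 12 CPM (SD, n = 4). The Rho-family GTPase Rhoj rose by 1.34 (SE 0.17, adjusted p = 0.0022), from 3.88 to 9.84 CPM, and the transcription factor Creb5 by 1.21, from 21.4 to 49.6 CPM. The executioner caspase Casp7 (1.36), the magnesium transporter relative Slc41a3 (1.15), the Wnt receptor Fzd6 (1.09), Thnsl2 (1.07) and Lect1 (1.05) rose as well. Falls were the GABA receptor subunit Gabrr2 (−1.45), Plekhg4 (−1.25), the vomeronasal receptor Vmn2r7 (−1.18), the Notch-ligand relative Dlk2 (−1.18), Ecel1 (−1.13), Fam194a (−1.10), the scavenger receptor Colec12 (−1.04, SE 0.16, from 13.4 to 6.47 CPM) and the potassium channel Kcnj14 (−1.01). Of the 27 genes named, 10 were called under every alternative: Cacna1g, Colec12, Creb5, Gfra1, Rhoj, Rorb, Slc41a3, Tenm3 and Flrt3 under its 2 identifiers.

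Synaptic adhesion and axon guidance genes rose at 6 of 59 members in R106W inhibitory nuclei, with 53 not passing and 8 rising adjusted over the list alone. They included Flrt3 (0.79, SE 0.079, adjusted p = 3.3e-04; 2 identifiers share the symbol and hold identical counts, so it is counted 2 times), the teneurin Tenm3 (0.57, adjusted p = 0.0054) and the netrin relative Ntng1 (0.58, adjusted p = 0.012). Sodium and calcium channels fell at 2 of 26 members, Cacna1g (−0.87, SE 0.11, adjusted p = 0.0022) and Cacnb3 (−0.61, adjusted p = 0.026), with 4 adjusted over the list alone. Grin2d was the 1 glutamate receptor gene of 24 that fell (−0.43, adjusted p = 0.044). Immediate early genes had a median of −0.32 with none called and 3 adjusted over the list alone; Arc stood at −0.84 (SE 0.25). Rorb (0.65), Kcnh5 (0.43) and the lysosomal gene Hexb (0.38) rose, and the interneuron glycoprotein Reln fell (−0.32, adjusted p = 0.027). Camera called adhesion genes (adjusted p = 0.0021), immediate early genes and sodium and calcium channels (0.0049 each), glutamate receptors (0.012), ribosomal proteins upward (0.019) and GABA receptors (0.025), and each had an adjusted p of 0.948 with an estimated correlation.

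Of 16121 genes tested in R106W against WT inhibitory nuclei, 235 rose and 133 fell; DESeq2 called 956, and only the 8 libraries of the 2 groups 180. The count was 103, 75, 781 and 112 without R106W replicates 1 to 4, and 190, 621 and 99 without WT replicates 2 to 4.

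T158M in inhibitory nuclei raised several of the same genes. Gfra1 rose by 1.07 (SE 0.11, adjusted p = 0.0013), to 103 ± 13 CPM (SD, n = 4), and Bmper, a secreted regulator of bone morphogenetic proteins, rose by 0.67 (SE 0.057, adjusted p = 1.3e-04), from 48.2 ± 2.4 to 76.4 ± 3.0 CPM. The spindle gene Spag5 (0.94), the receptor-kinase adaptor Gab1 (0.73), the neuropeptide receptor Qrfpr (0.72), the integrin Itga6 (0.71, from 23.6 to 38.5 CPM), the actin-binding Palld (0.67) and Adamtsl3 (0.67) also rose. Falls were AW551984 (−1.09), the cobalamin carrier Tcn2 (−1.02), Colec12 (−0.93), the membrane-repair gene Dysf (−0.91), the dynein chain Dnah7b (−0.80), Fgf11 (−0.70), Cacna1g (−0.62, adjusted p = 0.036) and the interneuron transcription factor Npas1 (−0.51). Adhesion genes rose at 4 of 59 members, Flrt3 (0.61) under its 2 identifiers, Ntng1 (0.61) and Tenm3 (0.46), with 55 not passing and 8 rising adjusted over the list alone. Immediate early genes had a median of 0.34, with 0 called either way and Egr2 at 0.86 (SE 0.27). Camera called both of these lists (adjusted p = 3.0e-07 each, and 0.723 with an estimated correlation), ribosomal proteins (1.6e-05) and respiratory chain genes (0.028; the adjusted p of both was 0.964 with an estimated correlation). Bmper, Dnah7b, Gab1, Gfra1, Itga6 and Flrt3 (2 identifiers) made up the 7 of 20 named genes called under every alternative. Of 16121 genes 30 rose and 14 fell. DESeq2 called 151 and only the 8 libraries 10. The count was 22, 14, 17 and 15 without T158M replicates 1 to 4, and 69, 26, 26 and 9 without WT replicates 1 to 4.

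Between R106W and T158M in inhibitory nuclei immediate early genes differed as a list. Of 17, 16 were lower in R106W (median −0.78), and 9 fell adjusted over the list alone, though none over all genes. This list kept its call with an estimated correlation (adjusted p = 8.6e-22, and 0.048 with an estimated correlation). Nuclear-retained noncoding RNAs were also lower (median −0.22, 0 passing adjusted over the list alone, adjusted p = 0.0031, and 0.21 with an estimated correlation). With edgeR 0 of 16121 genes were called, 1537 had an unadjusted p under 0.05, DESeq2 called 13, and 2 were called without T158M replicate 4. Against WT, 29 genes rose and 14 fell with both alleles, where independence would give 0.44 and 0.12. The WT libraries are shared here as well: the correlation across genes was 0.615 against 0.497 in simulations with no effect. With the WT libraries split it was 0.083, with on average 6.5 shared rises and 1 shared fall. Here too, 2 controls per allele instead of 4 lower the correlation and the number of calls by themselves. The covariance across genes was 0.0366, against 0.0218 in the simulations and 0.0064 with the WT libraries split.

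Mutant effects in the 2 cell classes overlapped. In R106W, 27 genes rose and 11 fell in both excitatory and inhibitory nuclei, where independence would give 1.21 and 0.70, and 1 went opposite ways. No libraries were shared. Among genes called in excitatory nuclei, 150 of 165 had the same sign in inhibitory ones. In T158M, 2 rose and 1 fell in both, against 0.028 and 0.016, and 34 of 38 had the same sign. Tested directly, the R106W effect was higher in inhibitory nuclei at 8 genes and lower at 0. They included Rhoj (difference 2.08, SE 0.34, adjusted p = 0.0094), Adamtsl3 (1.20), Medag (1.07), the vasohibin Vash2 (0.98), the polysialyltransferase St8sia2 (0.88) and the sialyltransferase St6gal1 (0.82, SE 0.12, adjusted p = 0.0054). The others, Gm20488 (1.07), whose span overlaps Medag, and 1810041L15Rik (0.70), were named after their values were seen. Adamtsl3, Medag, Rhoj and St6gal1 were called under every alternative. The T158M effect differed at 3 genes and was higher in inhibitory nuclei at each: Scn7a (1.40, SE 0.22, adjusted p = 0.026), St8sia2 (0.88) and Gt(ROSA)26Sor (1.84), an antisense transcript that overlaps the end of Thumpd3 and is therefore uncertain. With replicate number as a block among the excitatory libraries, where it was taken to pair WT with each allele, the effect differed at 16 genes for R106W and at 0 for T158M (Scn7a and St8sia2 at adjusted p = 0.073, Gt(ROSA)26Sor at 0.14).

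Among lists, the R106W effect on immediate early genes was lower in inhibitory nuclei (17 of 17 below 0, median −0.60, 1 adjusted over the list alone, adjusted p = 7.8e-09, and 0.676 with an estimated correlation), and that on adhesion genes higher (median 0.16, 2.9e-06, and 0.995 with an estimated correlation). For T158M the adhesion list was higher (median 0.12, 8.8e-08) and oligodendrocyte markers lower (median −0.28, 0.018), both with an adjusted p of 0.973 with an estimated correlation; each had 1 member adjusted over the list alone. Of 16713 genes, 983 and 548 had an unadjusted p under 0.05 for R106W and T158M; DESeq2 called 23 and 4, and no filter 16 for R106W. For R106W the count was 15 without excitatory R106W replicate 4, 13 without inhibitory R106W replicate 3 and 5 without inhibitory WT replicate 4. For T158M it was 2 without excitatory WT replicate 3 or inhibitory WT replicate 1, and 0 or 1 without any other library.

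Heterozygous females hold WT and mutant neurons in 1 brain, because of random X inactivation, and nuclei of both kinds were sorted and compared. In R106W heterozygotes Bmper rose in mutant nuclei by 1.04 (SE 0.079, adjusted p = 6.3e-04), from 63.1 ± 2.3 to 130 ± 1.6 CPM (SD, n = 2), and Bmpr1b, a receptor for bone morphogenetic proteins, rose by 0.86 (SE 0.078, adjusted p = 0.0019), from 57.2 to 104 CPM. Eya4 rose by 1.63 (SE 0.23, adjusted p = 0.020), the axon guidance ligand Ntn1 by 1.26, the homeobox gene Zfhx3 by 1.05, the Wnt-cleaving protease Trabd2b by 0.82, Tshz1 by 0.77, Ptgfrn by 0.74 and the guidance gene Sema5a by 0.52 (adjusted p = 0.015). Scn7a fell by 1.21 (SE 0.18, adjusted p = 0.025), from 5.05 to 2.18 CPM. The lectin Clec18a (−0.91), Sema3f (−0.86), Wdr66 (−0.79), the growth factor Fgf10 (−0.78), the axon-crossing receptor Robo3 (−0.74), the carbonic anhydrase Car12 (−0.74) and Soga1 (−0.73) fell with it. Sema5a was 1 of 60 adhesion genes to rise, with 59 not passing and 3 rising and 1 falling adjusted over the list alone (median 0.08, camera adjusted p = 1.7e-05, and 0.68 with an estimated correlation).

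Other lists had no called member in R106W mutant against WT nuclei. Inhibitory neuron markers had a median of 0.15 (1 member adjusted over the list alone, Maf standing at 0.60 with SE 0.14; adjusted p = 0.012, and 0.52 with an estimated correlation), immediate early genes −0.18 (0.012, and 0.875 with an estimated correlation) and neuropeptides −0.36 (0.033, and 0.852 with an estimated correlation). Of 16785 genes 14 rose and 12 fell. The protocol gives a single mouse per replicate, so WT and mutant nuclei of the same number were taken as paired, which their residuals bear out (correlation 0.79). With replicate number as a block 2016 genes were called, 1065 higher and 951 lower, neuropeptides lost their call (0.051) and GABA receptors gained one, lower (0.015, against 0.068). The block leaves 2 residual degrees of freedom, against 5 without it. In simulated data with the animal as a block, false calls made up 10.06% of the calls. DESeq2 called 119 genes and no filter 388. The count was 3 and 2 without mutant replicates 1 and 2, and 1 and 4 without WT replicates 1 and 2; Bmper alone of the 17 named genes was called under every alternative.

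In T158M heterozygotes many of the same genes passed. Bmper rose by 0.87 (SE 0.078, adjusted p = 0.0037), from 76.7 ± 5.3 to 140 ± 1.3 CPM (SD, n = 2), Eya4 by 1.40 (SE 0.20, adjusted p = 0.032), Tshz1 by 0.80, Bmpr1b by 0.71, Trabd2b by 0.69 and the secreted protein Nell1 by 0.62. Scn7a fell by 1.06, Dysf by 1.01, Wdr66 by 0.90, Car12 by 0.88, Robo3 by 0.72, the metalloprotease Adam19 by 0.70, Soga1 by 0.70 and the glypican Gpc5 by 0.55. The paralogs Xlr4a (1.45 ± 0.28 against 0.075 ± 0.0053 CPM) and Xlr4b (1.12 ± 0.33 against 0.026 ± 0.037 CPM) rose as well; reads of one can be counted for the other, and they lie on chromosome X within 5 Mb of Mecp2, being 2 of 84 tested genes there that rose, with 82 not passing (4 rising and 1 falling adjusted over the list alone). That set as a whole was not called (median 0.032, adjusted p = 0.436). WT and mutant nuclei of a heterozygote differ in which X chromosome is active. For genes on X, an effect of T158M therefore cannot be told apart from other differences between the 2 chromosomes.

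Endothelial and mural markers were all 9 above 0 in T158M mutant against WT nuclei (median 0.63, 0 called, adjusted p = 0.0018, and 0.619 with an estimated correlation), with Flt1 at 1.16 (SE 0.46) and Slco1a4 at 1.14 (SE 0.43). Ribosomal proteins (median 0.13) and respiratory chain genes (median 0.10) were called with 0 members passing (3.1e-04 each, and 0.734 with an estimated correlation). Sodium and calcium channels (median −0.07, 4 adjusted over the list alone) had an adjusted p of 0.011, and 0.698 with an estimated correlation; Cacna1g stood at −0.57 (SE 0.11), and Scn3b and Cacna1h at −0.52 each. Inhibitory markers (median 0.16) and adhesion genes (median 0.020) had 0.036 each, and 0.665 and 0.734 with an estimated correlation. Of 16785 genes 12 rose and 8 fell. With replicate number as a block, for the same pairing by mouse (correlation 0.79), 2735 were called, 1209 higher and 1526 lower, and immediate early genes (0.027, against 0.288), glutamate receptors (0.025, against 0.236) and GABA receptors (0.017, against 0.108) were called as well, all lower. Here too the block leaves 2 residual degrees of freedom. DESeq2 called 88 and no filter 371. The count was 7 without WT replicate 1 and 0 without WT replicate 2 or either mutant replicate, so none of the 16 named genes was called under every alternative. With no shared libraries, the 2 heterozygote comparisons had 9 rises and 6 falls in common, where independence would give 0.010 and 0.0057, and all 26 genes called in R106W had the same sign in T158M.

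Across the 6 comparisons of mutant with WT sorted nuclei, 23 of 15022 genes tested in all were called in at least 3, 13 of them higher each time and 10 lower each time. This selection was made after the values were seen. The R106W and T158M comparisons of each male cell class share their WT libraries, so recurrence within a class is not independent, and the number expected without an effect was not computed. Bmper was higher in all 6, by 0.49 to 1.04; in male excitatory nuclei it went from 73.7 ± 4.8 CPM in WT to 104 ± 7.6 in R106W and 104 ± 6.5 in T158M (SD, n = 4). Ptgfrn, which binds a prostaglandin receptor, was higher in 5, and Tshz1 and the giant cadherin Fat1 in 4. Scn7a was lower in 4 and stood at −0.10 and 0.14 in inhibitory nuclei; Wdr66 was also lower in 4. Cacna1g was called lower in 3 and lay below 0 in all 6, from −0.87 to −0.33. The glycine receptor subunit Glra3, Dysf, Clec18a, Cntnap5c, Frmd3, March4 and C77370 were lower in 3, and Eya4, Bmpr1b, Qrfpr, Mtus1, Trp53bp2, Zak, Dpy19l1, the cholesterol exporter Abca1 and the amino acid transporter Slc16a10 higher in 3. Bmper (ENSMUSG00000031963) spans 23223076 to 23485202 on chromosome 9 of mm10, and Scn7a (ENSMUSG00000034810) spans 66673425 to 66784914 on chromosome 2. Of the genes called in male R106W excitatory nuclei, 164 of 173 had the same sign in the R106W heterozygotes, with 6 rises and 4 falls called in both (independence would give 0.074 and 0.065). For T158M it was 39 of 41, with 3 rises and 2 falls (0.0097 and 0.013).

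**Figure D1:**
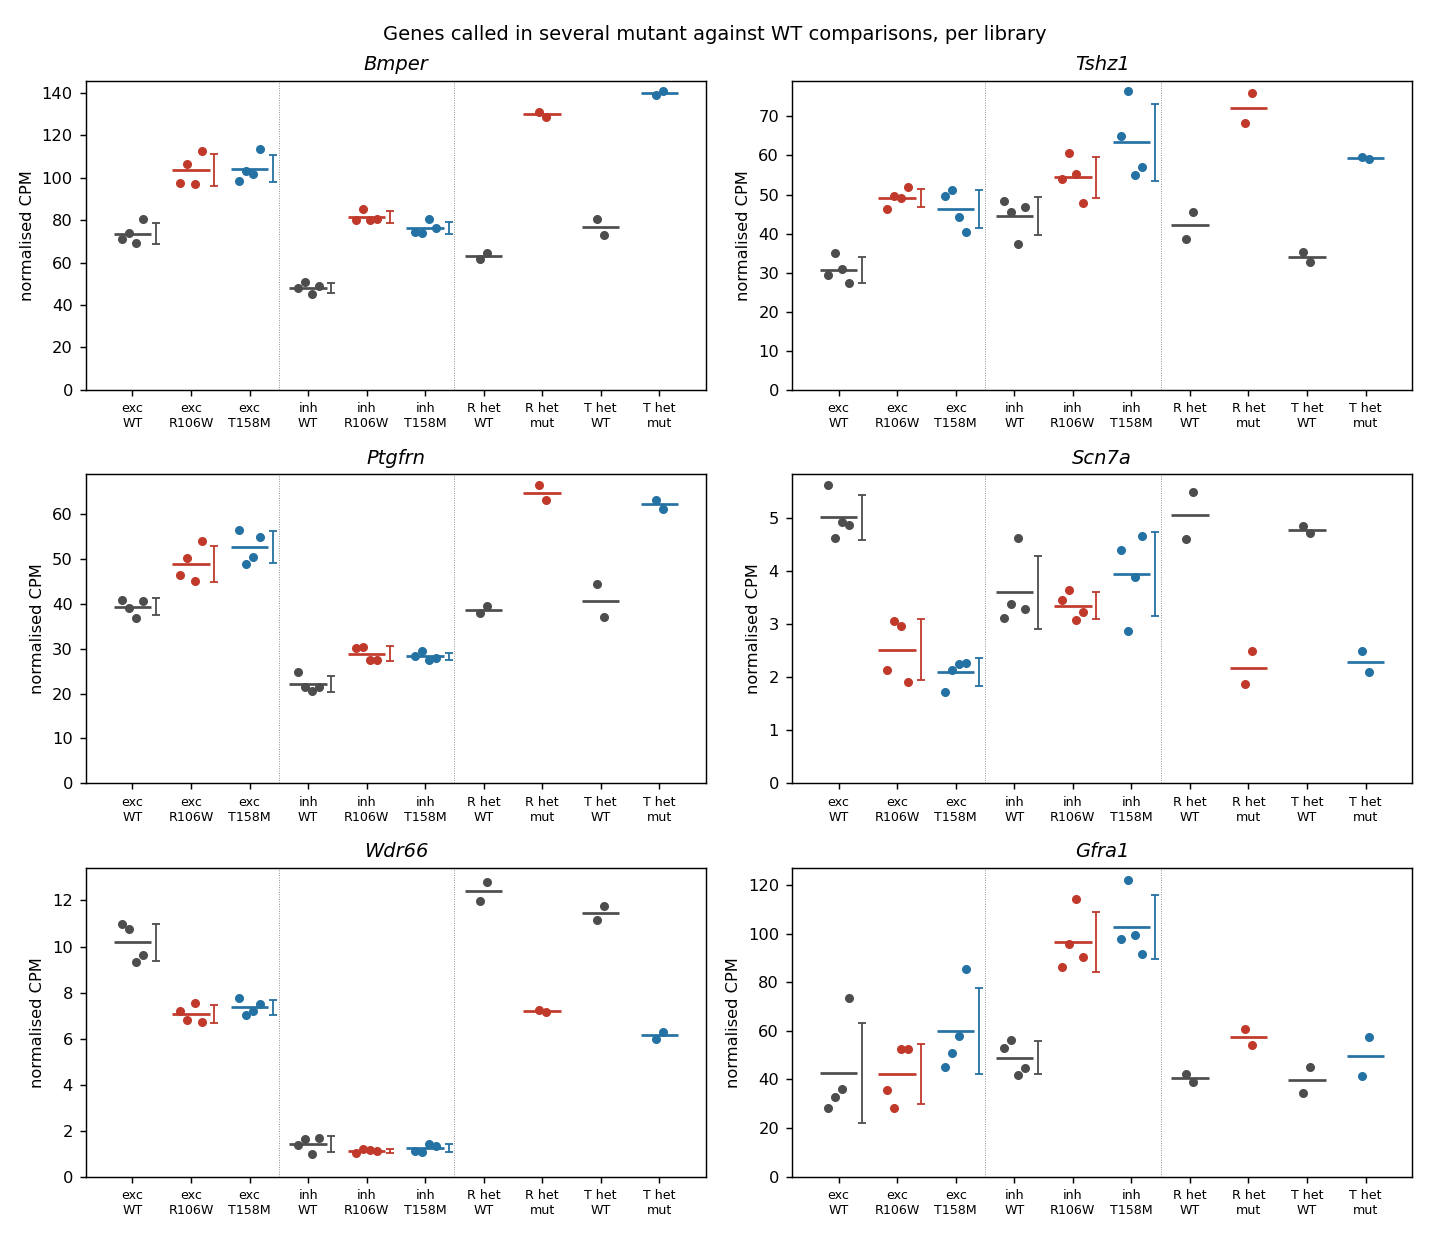
Normalised CPM of Bmper, Tshz1, Ptgfrn, Scn7a, Wdr66 and Gfra1 in each library of sorted nuclei, with group means and, for groups of 4, the SD. Bmper means are 73.7, 104 and 104 in male excitatory WT, R106W and T158M nuclei.

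WT-expressing nuclei of heterozygotes, set against WT/WT females, ask whether cells with normal MeCP2 differ when their neighbours are mutant. In R106W heterozygotes immediate early genes were higher in 17 of 17 cases (median 0.73); 6 rose, 11 did not pass and 16 rose adjusted over the list alone. They included Npas4 (1.42, SE 0.21, adjusted p = 0.015), Nr4a3 (1.36, adjusted p = 0.011), Btg2 (1.63) and Dusp1 (0.80), and the related matrix gene Cyr61 rose by 2.13 (SE 0.22, adjusted p = 0.0019), from 1.98 to 8.71 CPM. Glucocorticoid-responsive genes split: the chaperone Fkbp5 fell by 1.11 (SE 0.10, adjusted p = 9.8e-04) and Zbtb16 by 0.58, while Per1 rose by 0.50 (10 of 13 not passing, 1 up and 2 down adjusted over the list alone, median −0.14). The developmental regulators Sim1 (1.14 ± 0.15 against 0.027 ± 0.039 CPM), Ebf2 (1.03 ± 0.35 against 0.072 ± 0.053 CPM) and Nr2f2 (1.92), and Baiap3 (2.37), rose. The regulators Rfx4 (−2.47), Gli2 (−2.12), Tcf7l2 (−2.07) and Gli3 (−1.55), the phagocytic receptor Mertk (−2.30, SE 0.23, from 4.29 to 0.868 CPM), Plekhg1 (−1.97) and the thyroid hormone deiodinase Dio2 (−1.89) fell. These falls were at low levels, with a mean log2 CPM over the female libraries from 0.034 (Rfx4) to 1.63 (Mertk). Whether they arose in neurons or in glial nuclei carried into the sort was not tested. Mid1 rose by 2.60 (SE 0.14, adjusted p = 1.1e-05) and Erdr1 by 3.96; both are uncertain, since Mid1 spans the pseudoautosomal boundary and Erdr1 is annotated on Y.

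Oligodendrocyte, precursor and astrocyte markers were lower in the same R106W comparison, and microglia markers were not (9 tested, median 0.0063, 0 called, adjusted p = 0.937). Of 14 oligodendrocyte markers Mobp fell (−1.20, adjusted p = 0.048), 13 did not pass, and 5 fell adjusted over the list alone (median −0.77). Bcas1 fell among 6 precursor markers (−2.39, adjusted p = 0.023, 2 adjusted over the list alone, median −0.48). None of 13 astrocyte markers passed (median −0.23). Nxph1 fell among 18 inhibitory markers (−0.61, adjusted p = 0.041, 3 adjusted over the list alone, median −0.017). With an estimated correlation no list kept its camera call: the adjusted p went from 7.7e-33 to 0.282 with an estimated correlation for immediate early genes, from 1.0e-08 to 0.282 for oligodendrocyte markers, from 0.0068 to 0.282 for precursors, from 0.040 to 0.319 for astrocytes, from 0.023 to 0.29 for glucocorticoid-responsive genes and from 0.046 to 0.319 for inhibitory markers. Potassium channels (median −0.10, 1 adjusted over the list alone, 0.041) and glutamate receptors (median −0.11, 0.0032) went to 0.319 and 0.535. Of 16785 genes 58 rose and 34 fell, and Cyr61, Erdr1, Fkbp5, Mertk, Mid1 and Sim1 were called under every alternative. DESeq2 called 181 and no filter 573; the count was 19 and 34 without replicates 1 and 2 of the WT nuclei, and 43 and 19 without WT/WT replicates 1 and 2.

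Mutant R106W nuclei against WT/WT females gave 147 rises and 115 falls. Immediate early genes again lay above 0 in 17 of 17 cases (median 0.58), with 4 rising, 13 not passing and 12 rising adjusted over the list alone. The WT/WT libraries are those used for the WT nuclei, so this is not an independent repeat. Oligodendrocyte markers had a median of −0.73 with 2 falling, astrocyte markers −0.27 with 1 falling, precursor markers −0.46 with 1 falling, and sodium and calcium channels −0.027 with 2 falling. The camera adjusted p of these 5 lists was 4.1e-16, 9.5e-06, 0.0055, 0.044 and 0.041, and with an estimated correlation it was 0.375 for the first 4 and 0.424 for the channels. Without a filter 975 genes were called; the count was 38 and 76 without mutant replicates 1 and 2, and 79 and 85 without WT/WT replicates 1 and 2.

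WT nuclei of T158M heterozygotes differed from WT/WT females at 7 genes. Pou6f2, a homeobox transcription factor, fell by 0.60 (SE 0.077, adjusted p = 0.018), from 104 ± 2.4 to 68.9 ± 3.9 CPM (SD, n = 2), and it was the 1 gene that fell in WT nuclei of both heterozygotes, which share the WT/WT libraries. The inhibitory Fc receptor Fcgr2b rose from 0.062 ± 0.010 to 1.99 ± 0.14 CPM. The other 5, named after their values were seen, all lie on chromosome 12: Gm4425, Gm10476, Gm20472 and Gm20474 rose and the pseudogene 3110053B16Rik fell (−0.71). Immediate early genes lay above 0 in 17 of 17 cases (median 0.39, 0 called, adjusted p = 6.6e-12, and 0.824 with an estimated correlation). The R106W comparison uses the same WT/WT libraries, so this does not repeat its result for these genes independently. None of 24 DNA methylation and NCoR/SMRT genes passed (adjusted p = 0.731). Of 16785 genes 5 rose and 2 fell. DESeq2 called 18 and no filter 164; the count was 0 without WT/WT replicate 1 and 4 without WT/WT replicate 2, and it was 5 without either replicate of the WT nuclei. Mutant T158M nuclei against WT/WT females gave 33 rises and 60 falls. Ribosomal proteins (median 0.18, 74 of 78 above 0, adjusted p = 9.4e-06) and respiratory chain genes (median 0.12, 67 of 72 above 0, 7.3e-05) had 0 members called, and endothelial markers had a median of 0.88 (0.0053); with an estimated correlation the adjusted p was 0.704, 0.704 and 0.476. DESeq2 called 245 and no filter 945; the count was 14 and 13 without mutant replicates 1 and 2, and 42 and 52 without WT/WT replicates 1 and 2.

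In unsorted male cortex, whole-cell RNA of R106W mice differed from WT at 6 genes. Ide, the insulin-degrading enzyme, rose by 1.04 (SE 0.074, adjusted p = 7.1e-04), from 66.6 ± 2.1 to 137 ± 1.7 CPM (SD, n = 2), and Btaf1, a regulator of the TATA-binding protein, rose by 0.94 (SE 0.080, adjusted p = 0.0025). They are near neighbours on chromosome 19, Btaf1 (ENSMUSG00000040565) spanning 36926079 to 37012752 and Ide (ENSMUSG00000056999) 37268743 to 37337852. The contactin Cntn4 rose by 0.75 (SE 0.070, adjusted p = 0.0046), the astrocyte lyase Etnppl by 1.88 (SE 0.21, adjusted p = 0.016) and Gt(ROSA)26Sor (ENSMUSG00000086429; chromosome 6, 113067428 to 113077333) by 3.03 (SE 0.18, adjusted p = 3.2e-04). The noncoding RNA 9330185C12Rik, named after its values were seen, fell (−3.54). Cntn4 was the 1 of 60 adhesion genes to rise; 46 lay above 0, and 24 rose adjusted over the list alone (median 0.15). No member passed among neuropeptides (median −0.33, 4 adjusted over the list alone), where Sst stood at −0.60 (SE 0.084), Tac1 at −0.90 (SE 0.17) and Adcyap1 at −0.64 (SE 0.15). The same held for precursor markers (median −0.26, 2 adjusted over the list alone), microglia markers (13 of 13 below 0, median −0.20, 1 adjusted over the list alone) and endothelial markers (median −0.18). Camera called adhesion genes (adjusted p = 2.9e-13), neuropeptides (1.3e-08), precursors (8.6e-05), microglia (1.8e-04) and endothelial markers (0.0054); with an estimated correlation the adjusted p was 0.603, 0.563, 0.563, 0.762 and 0.762. Of 16876 genes 5 rose and 1 fell, and the 5 named genes were called under every alternative. DESeq2 called 71, no filter 588, and 1 fit over the 12 cortex libraries 10; the count was 222 and 118 without WT replicates 1 and 2, and 25 without R106W replicate 2.

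Nuclear RNA of the same genotypes had 1 called gene of 17229, Gt(ROSA)26Sor, which rose by 2.91 (SE 0.17, adjusted p = 3.6e-04). Oligodendrocyte markers were lower without a called member (median −0.40, 7 adjusted over the list alone), with Mag at −0.73 (SE 0.13), as were precursor markers (median −0.38, 3 adjusted over the list alone), with Pdgfra at −0.67 (SE 0.13). Neuropeptides (median −0.37) and ribosomal proteins (75 of 78 below 0, median −0.13) were lower too, and endothelial markers (11 of 12 above 0, median 0.41) and adhesion genes (median 0.08) higher. Camera adjusted p was 9.3e-09, 6.9e-05, 2.5e-04, 0.0013, 1.2e-04 and 7.6e-04 for these 6 lists, and with an estimated correlation it was 0.761 for each but ribosomal proteins, with 0.821. Nuclear WT replicate 2 had 193.7 M counts, and without it 573 genes were called, the oligodendrocyte and precursor lists kept their calls (5.8e-07 and 0.0085), and endothelial markers, neuropeptides, adhesion genes and ribosomal proteins did not (0.545, 0.345, 0.101 and 0.19, the last in the opposite direction). Without it DNA methylation and NCoR/SMRT genes (adjusted p = 0.017, against 0.267) and genes over 100 kb (0.0012, against 0.186) were also called, both lower. DESeq2 called 63, no filter 307, RLE size factors 6 and 1 fit over the cortex libraries 42; the count was 1134 without WT replicate 1, and 37 and 72 without R106W replicates 1 and 2.

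**Figure D2:**
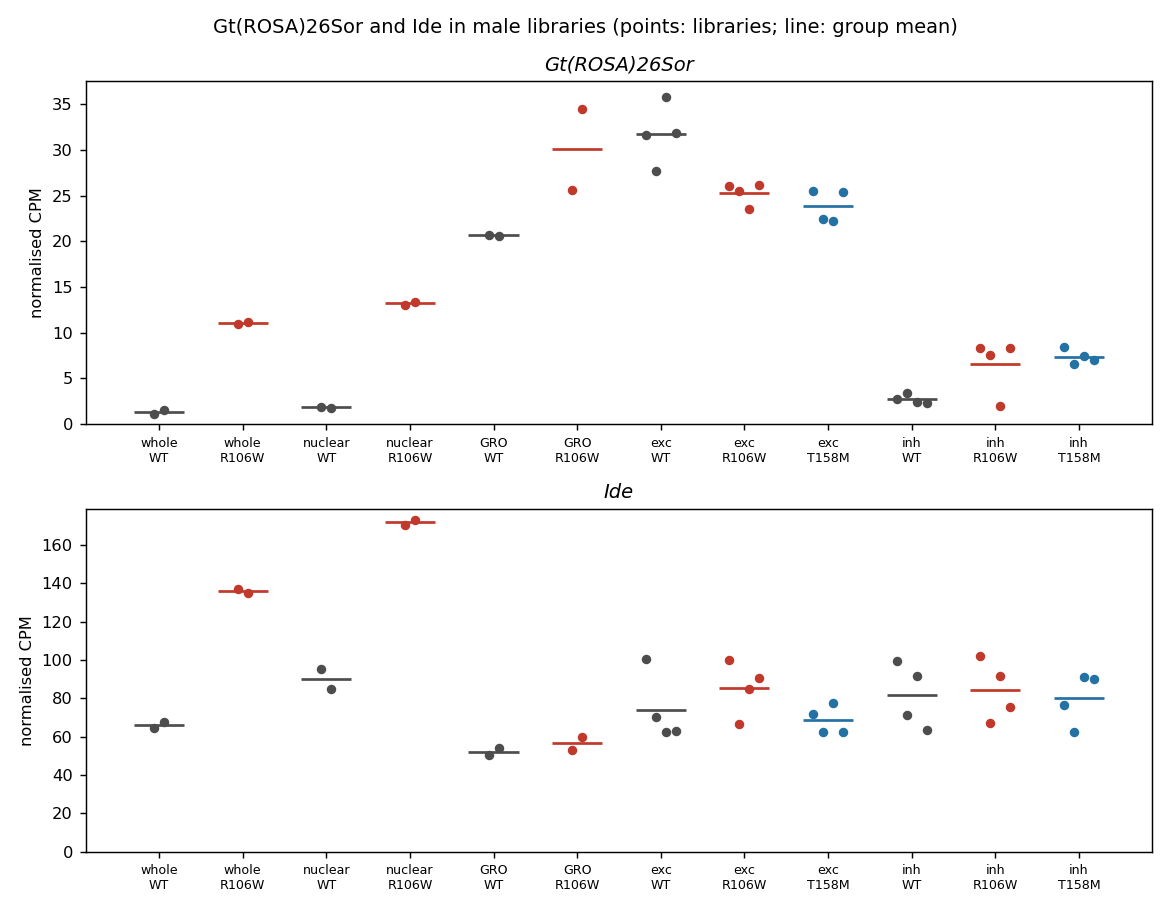
CPM of Gt(ROSA)26Sor and Ide in each male library, with group means as lines. Gt(ROSA)26Sor stands at 10.97 and 11.2 in the R106W whole-cell libraries against 1.15 and 1.58 in WT, and Ide at 137 and 135 against 64.7 and 67.6.

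GRO-seq, which reads ongoing transcription, gave 0 called genes of 19327 with edgeR quasi-likelihood, while 2704 had an unadjusted p under 0.05 and DESeq2 called 304. Neuronal receptor and channel lists lay below WT in R106W. Glutamate receptors had a median of −0.22 (6 of 24 adjusted over the list alone), with Grm7 at −0.36 (SE 0.081) and Grin2b at −0.31 (SE 0.079). GABA receptors had −0.20 (6 of 14 adjusted over the list alone), with Gabbr2 at −0.55, potassium channels −0.17 (2 of 29), adhesion genes −0.14 (3 up and 9 down of 60), sodium and calcium channels −0.084 (5 of 26) and excitatory markers −0.12 (1 of 19). Markers of other cells were lower as well: endothelial −0.64 (12 of 12 below 0, 5 adjusted over the list alone), precursors −0.53 (6 of 8), microglia −0.47 (2 of 13), astrocytes −0.28 (1 of 13) and oligodendrocytes −0.13 (3 of 14). Immediate early genes had 0.11 (1 of 17). Camera adjusted p ran from 5.0e-07 for endothelial markers to 0.037 for immediate early genes, and with an estimated correlation from 0.272 to 0.636. No filter gave 958 genes and 1 fit over the 12 cortex libraries 83; the count was 3837 and 685 without R106W replicates 1 and 2, and 7 without either WT replicate.

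The R106W effect differed between assays at few genes. It was higher in whole-cell RNA than in GRO-seq at Gt(ROSA)26Sor (2.49, SE 0.25, adjusted p = 4.7e-04), Ide (0.92, adjusted p = 0.035) and Btaf1 (1.06, adjusted p = 0.045), and higher in nuclear RNA than in GRO-seq at Gt(ROSA)26Sor (2.35) and lower at the calcium channel subunit Cacna2d4 (−1.68) and the repeat-rich Gm10800 (−4.75); all were named after their values were seen. Adhesion genes were higher in whole-cell RNA than in GRO-seq (median 0.32, 49 of 60 above 0, 17 adjusted over the list alone, adjusted p = 1.2e-19, and 0.206 with an estimated correlation), as were potassium channels (median 0.20, 5.4e-06, and 0.333 with an estimated correlation). Endothelial markers were higher in nuclear RNA than in GRO-seq (median 0.89, 12 of 12 above 0, 5 adjusted over the list alone, 1.3e-14, and 0.326 with an estimated correlation). In whole-cell against nuclear RNA, ribosomal proteins were higher (78 of 78 above 0, median 0.20, 3.0e-11, and 0.898 with an estimated correlation) and endothelial markers lower (median −0.59, 3.0e-11, and 0.54 with an estimated correlation), with 0 members passing adjusted over the list alone. That comparison gave 0 called genes of 20435 with edgeR, 0 with DESeq2 and 378 at an unadjusted p under 0.05, while no filter gave 25 and leaving out nuclear WT replicate 1 or nuclear R106W replicate 2 gave 23 or 1. For nuclear RNA against GRO-seq (3 genes), DESeq2 gave 21 and no filter 241, and the count was 119 without nuclear WT replicate 1, 68 without GRO-seq R106W replicate 1 and 1 without any other nuclear or GRO-seq library. For whole-cell RNA against GRO-seq (3 genes), DESeq2 gave 113 and no filter 178, and the count was 17 and 2 without GRO-seq R106W replicates 1 and 2 and 1 without any other.

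Genes spanning over 100 kb, many of them neuronal, were examined because long genes have been linked to MeCP2. In male excitatory nuclei their median lay below that of other genes by −0.114 in R106W (38 rose, 38 fell and 2261 did not pass of 2337; 66 rose and 99 fell adjusted over the list alone) and by −0.0718 in T158M (4 rose, 17 fell), with camera adjusted p = 1.9e-07 and 1.2e-06, and 0.687 and 0.521 with an estimated correlation. In inhibitory nuclei the shifts were −0.0474 for R106W (73 rose and 38 fell of 2363, adjusted p = 0.341) and −0.0328 for T158M (19 rose, 8 fell, 0.291). Mutant against WT nuclei in heterozygotes gave 0.0542 for R106W (10 rose, 5 fell, adjusted p = 4.7e-05, and 0.875 with an estimated correlation) and −0.0239 for T158M (7 rose, 3 fell, 0.715). In cortex it was 0.0618 in whole-cell RNA (1 rose, adjusted p = 4.4e-04, and 0.762 with an estimated correlation), 0.0336 in nuclear RNA (0 called, 0.186) and −0.145 in GRO-seq (0 called, 37 up and 138 down adjusted over the list alone, 1.4e-09, and 0.539 with an estimated correlation). Tested directly, long genes were higher in whole-cell RNA than in GRO-seq (median difference 0.16, adjusted p = 6.3e-16, and 0.437 with an estimated correlation).

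Single libraries moved these shifts. Without WT replicate 4 the shift was −0.0209 for T158M excitatory nuclei and 0.0043 for T158M inhibitory nuclei; without WT nuclei replicate 1 it was −0.0236 for R106W heterozygotes, and without mutant replicate 2 0.0069. For T158M heterozygotes it was 0.0377 and 0.0368 without mutant replicate 1 and WT nuclei replicate 2, and for nuclear RNA −0.0025 and −0.0716 without R106W replicate 2 and WT replicate 2. Whole-cell RNA gave 0.0167 without R106W replicate 1. Shifts whose camera p had not passed did pass in inhibitory nuclei for R106W (−0.0648, −0.0614, −0.0603 and −0.0945 without R106W replicates 2 and 3 and WT replicates 1 and 3) and for T158M (−0.0601, −0.0417 and −0.0763 without T158M replicate 2 and WT replicates 1 and 3). They also passed in T158M heterozygotes (−0.0676 and −0.0751 without mutant replicate 2 and WT nuclei replicate 1) and in nuclear RNA (0.0742 and 0.139 without R106W replicate 1 and WT replicate 1).

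**Figure D3:**
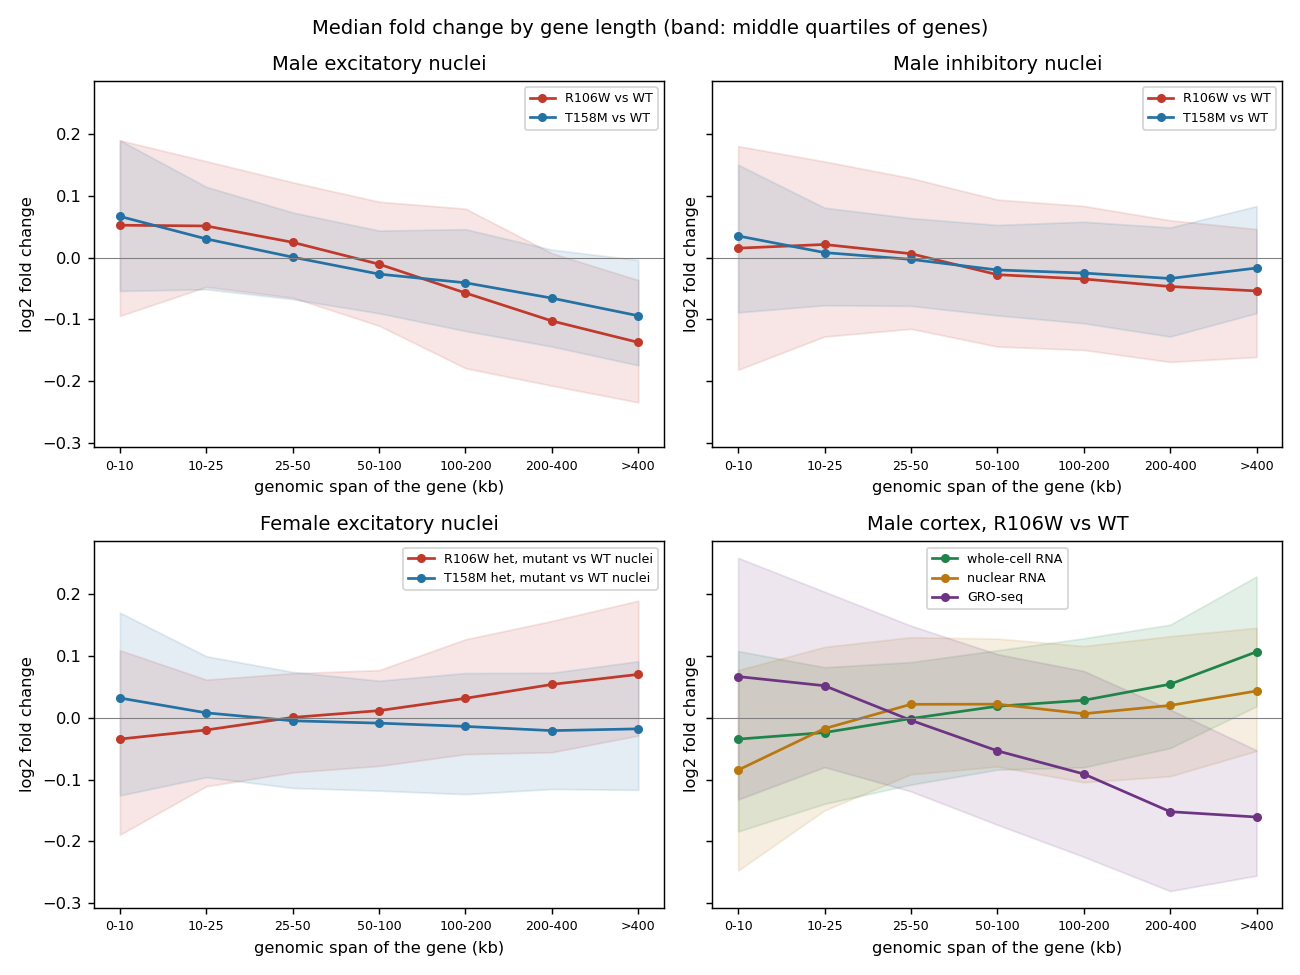
Median log2 fold change (mutant minus WT) of genes grouped by genomic span in kb, with the middle quartiles of genes as bands. Genes over 100 kb lie below other genes by −0.145 in GRO-seq and above them by 0.0618 in whole-cell RNA.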

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

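The dissection and depth tests below were planned before their results were seen; the other tests, including every count of regrouped samples, were chosen only after the result was seen.

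Whole-cell cortex RNA of R106W mice held more Ide (log2 1.04), Btaf1 (0.94) and Gt(ROSA)26Sor (3.03) than WT, and their R106W effect was higher than in GRO-seq by 0.92, 1.06 and 2.49, and for Gt(ROSA)26Sor by 2.35 in nuclear RNA against GRO-seq. Fgfbp3, the nearest neighbour of Btaf1, moved with them without passing (0.73, SE 0.18, in whole-cell and 1.22, SE 0.23, in nuclear RNA), but its reads are argued against as the source, since it reached 5.37 CPM at most while Ide and Btaf1 gained at least 69.7 (SE 1.90). Reads of other neighbours are argued against too: the highest change among Tnks2, Cpeb3 and March5 was 0.15 (SE 0.11, March5 in nuclear RNA), and among Thumpd3 and Setd5, beside Gt(ROSA)26Sor, −0.012 (SE 0.077). An effect of genotype alike in every cell and assay is argued against as well. For Gt(ROSA)26Sor, excitatory nuclei stood at −0.31 (SE 0.081) in R106W, while inhibitory nuclei stood at 1.27 (SE 0.32, adjusted p = 0.053) in R106W and 1.44 (SE 0.32, adjusted p = 0.087) in T158M. For Ide and Btaf1, values in R106W excitatory and inhibitory nuclei and in GRO-seq lay below the whole-cell value by at least 0.81 (SE 0.16, Ide in excitatory nuclei, at 0.23). An effect of R106W on RNA stability, or in cells outside the sorted classes, was not tested and stays open. Gt(ROSA)26Sor did not follow genotype in every library: inhibitory R106W replicate 3 stood at 1.96 CPM, below every inhibitory WT library. The other inhibitory R106W replicates stood at 7.56 to 8.33 CPM. WT libraries of this gene stood at 27.7 to 35.8 CPM in excitatory nuclei, but at 1.73 and 1.90 in cortex nuclear RNA. Whether mice differed in Cre or BirA alleles was not tested, so such a difference stays open for this gene too. A variant in copy number carried by some mice of either genotype may explain Ide: over 34 sorted libraries its SD within groups was 0.309, at the 98.7th percentile of 2803 genes at a like level, and within male excitatory WT it ran from 62.3 to 101 CPM. The SD of Btaf1 was 0.183, at the 89.8th percentile of 1874 genes. Cpeb3 and March5 lie between Btaf1 and Ide and stood at 0.12 (SE 0.078) and −0.036 (SE 0.077) in whole-cell RNA. The values thus do not show 1 gain over the whole stretch.

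WT nuclei of R106W heterozygous females differed from those of WT/WT females at 92 genes, Sim1 among them. Camera called immediate early genes higher and oligodendrocyte markers lower, but not with an estimated correlation (adjusted p = 0.282 each). The median of microglia markers lay 0.776 (SE 0.257) above that of oligodendrocyte markers, where fewer glial nuclei of every type would lower both. This SE, like that of the region markers below, is taken over marker genes, not animals. It does not measure the spread between the 2 animals per genotype, so fewer glial nuclei of every type are not excluded. More tissue from medial amygdala or hypothalamus could raise Sim1, and the tested markers of these regions had a median of 0.73 (SE 0.34), but only 6 of 18 were tested, 0 were called, and camera gave p = 0.020 and 0.076 with an estimated correlation; Lhx9 stood at 1.42, Trh at 1.23, Esr1 at 0.98, Nr5a1 at 0.49, Slc17a6 at −0.038 and Ar at −0.19. Neurod6, an excitatory marker named after its values were seen, stood at 6.38 and 5.67 CPM in the WT/WT libraries. In R106W heterozygotes it stood at 2.03 and 1.73 CPM in WT nuclei and 2.57 and 2.27 in mutant nuclei. In T158M heterozygotes, replicate 1 had 6.89 (WT nuclei) and 7.64 (mutant nuclei), and replicate 2 had 1.93 and 3.36. Animals thus differed at this gene within 1 genotype, and a difference in Cre or BirA alleles was not tested. With 2 animals per genotype, a difference between animals or batches cannot be told apart from an effect of mutant neighbours. That effect, the biological explanation the design gives, stays open.

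Genes over 100 kb lay lower in R106W GRO-seq and higher in R106W whole-cell RNA, a difference of 0.199. With the 8 libraries thinned to the lowest total the difference was 0.198. Thinning keeps the proportions of genes within a library, so this shows only that the number of counts did not set the difference. A difference in composition that goes with depth was not tested. A bias with gene length that differs from library to library may explain it, as the largest shift between 2 whole-cell libraries of 1 group was 1.39 times the genotype shift. A single library cannot be told apart as a source, since the difference was lowest, at 0.110, without GRO-seq R106W replicate 2, and highest, at 0.288, without GRO-seq R106W replicate 1. An effect of R106W on long genes, by transcription or by RNA stability, was not separated from these and stays open.

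Effects differed between cell classes or assays at other genes. The R106W effect was higher in inhibitory than excitatory nuclei at Rhoj (2.08), Adamtsl3 (1.20), Gm20488 (1.07), Medag (1.07), Vash2 (0.98), St8sia2 (0.88), St6gal1 (0.82) and 1810041L15Rik (0.70). The T158M effect was higher in inhibitory nuclei at Gt(ROSA)26Sor (1.84), Scn7a (1.40) and St8sia2 (0.88), and none of the 3 was called with replicate number as a block among the excitatory libraries. The R106W effect was lower in nuclear RNA than in GRO-seq at Gm10800 (−4.75) and Cacna2d4 (−1.68).

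Single samples stood far from the other 3 of their group in 17 of 231 cases, and chance marks about 1 in 20. Mid1 was at 550.4 CPM in excitatory WT replicate 4 and at 8.90 in T158M replicate 1, Btaf1 at 190.4 in T158M replicate 3, and genes over 100 kb took 71.5% of counts in T158M replicate 4. Excitatory R106W replicate 3 had Armc4 at 6.85 CPM and Cacna1g at 58.7, and replicate 4 had Creb5 at 3.11, Rhoj at 3.23 and Gab1 at 5.36. In inhibitory R106W nuclei, replicate 3 had Gt(ROSA)26Sor at 1.96 CPM and Colec12 at 8.86, replicate 4 Abca1 at 98.0 and Gab1 at 12.96, and replicate 2 Bmper at 85.5. Creb5 was at 49.0 CPM in inhibitory T158M replicate 3. Tnc was at 1.16 CPM in excitatory WT replicate 3 and 1.14 in inhibitory WT replicate 1.

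Regrouping the same 8 libraries into 4 against 4 gave 35 splits, the real one included. For R106W in inhibitory nuclei 1 of the 35 splits, the real one, gave as many as 368 genes (highest other 61 higher and 45 lower). For inhibitory against excitatory WT nuclei it was 1 of 35 too (9823, highest other 329). Both argue against chance, but 1 of 35 is the smallest share that 35 splits can give. As the tests were also chosen after the results were seen, chance is not taken as excluded. For R106W in excitatory nuclei 1 of 35 gave as many as 173 genes (highest other 2), and for T158M there 2 of 35 gave as many as 41, the highest other, 78, setting WT replicate 1 and T158M replicates 1 to 3 against the rest. Because these libraries were taken as paired, the splits to compare are the 8 that part all 4 pairs, too few for a share under 0.05. Without a block, the others among them gave 0 genes, for R106W and for T158M. With replicate as a block the highest other gave 0 genes for R106W, where the real split gave 653. For T158M it gave 1, where the real split gave 112. For R106W against T158M in excitatory nuclei it was 1 of 35, but on a margin of 1 gene (2, highest other 1), and the count was 1 without R106W replicate 2, so chance is not taken as excluded. Nor can it be excluded for T158M in inhibitory nuclei, where 2 of 35 gave 44 or more; the highest other, 164, exchanged WT replicates 2 and 3 with T158M replicates 1 and 2 and points to a structure among these libraries other than genotype. For R106W against T158M in inhibitory nuclei 0 genes were called, so 35 of 35 splits gave as many and nothing is tested (highest other 295). For differences between cell classes, 9 of 100 regroupings gave as many as 8 genes for R106W (highest other 1126) and 7 of 100 as many as 3 for T158M (highest other 491), but regrouping within each class does not keep the genotype effect that both classes share, so these splits cannot tell whether chance gave the differences.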

How the results depend on the processing

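Crossed replicate numbers as a block, for nuclear RNA, number across genotypes as a block, for heterozygotes against WT/WT females, and number among excitatory libraries as a block, for effects between cell classes, were the alternatives chosen only after the result was seen. The cause of the changes below was not tested, except that leaving out libraries leaves fewer samples.

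RLE size factors left 20 of 21 counts of called genes within 1.5 times their value and gave 6 instead of 1 in nuclear RNA. DESeq2 raised 17 counts beyond that, and left 4 within it. In male excitatory nuclei it gave 475 for R106W, 160 for T158M and 58 between them, and in inhibitory nuclei 956, 151 and 13. The R106W effect differed between cell classes at 23 genes. In R106W heterozygotes DESeq2 gave 119 for mutant against WT nuclei and 181 for WT nuclei against WT/WT, in T158M heterozygotes 88 and 18, and 245 for mutant nuclei against WT/WT. In cortex it gave 71 in whole-cell RNA, 63 in nuclear RNA, 304 in GRO-seq, 21 for nuclear RNA against GRO-seq and 113 for whole-cell RNA against GRO-seq.

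No filter on low counts also raised 17 counts and left 4. It gave 405, 114 and 89 in excitatory nuclei, 3 between alleles in inhibitory nuclei and 16 for the R106W effect between classes. In R106W heterozygotes it gave 388, 573 and 975 (mutant against WT, WT against WT/WT, mutant against WT/WT), and in T158M heterozygotes 371, 164 and 945. In cortex it gave 588, 307 and 958 (whole-cell, nuclear, GRO-seq), and 241, 25 and 178 for nuclear RNA against GRO-seq, whole-cell against nuclear RNA, and whole-cell RNA against GRO-seq. The 8 libraries of the 2 groups alone gave 36 and 180 for R106W in excitatory and inhibitory nuclei and 10 for T158M in inhibitory nuclei.

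With replicate as a block the counts were 653, 112 and 116 in excitatory nuclei, 210 for R106W in inhibitory nuclei, 0 for the T158M effect between classes (by number within genotype), 2016 and 2735 for mutant against WT nuclei in R106W and T158M heterozygotes, 1441 in whole-cell and 94 in nuclear RNA, and 1 for nuclear and for whole-cell RNA against GRO-seq. Crossed numbers gave 1264 in nuclear RNA. Number among the excitatory libraries alone gave 16 for the R106W and 0 for the T158M effect between classes, ended the calls of the 3 genes named for T158M and changed no list call there. One fit over the 12 cortex libraries gave 10, 42 and 83. For heterozygotes against WT/WT, number within genotype could not be fitted, and number across genotypes gave 356 and 764 in R106W (WT nuclei, mutant nuclei) and 11 and 894 in T158M. Numbers were taken to pair WT and mutant nuclei of a heterozygote, as the protocol gives 1 mouse per replicate (correlation 0.79 in each). Elsewhere, with 2 libraries per group both pairs share 1 correlation, and numbers were not taken to pair the libraries: it was 0.52 and 0.43 between WT/WT and the R106W nuclei, 0.13 and 0.086 between WT/WT and the T158M nuclei, 0.41 in whole-cell RNA, −0.50 in nuclear RNA and −0.034 in GRO-seq. In inhibitory nuclei 2 of 4 pairs of WT with R106W and 1 of 4 with T158M lay over 0.1, as did 1 of 4 between the alleles in either class. Between excitatory and inhibitory nuclei of 1 genotype it was 3 of 4 in WT, 3 of 4 in R106W and 2 of 4 in T158M, so not every pair passed. In excitatory nuclei all 4 pairs of WT with each allele lay over 0.1, and 3 of 4 correlated best with their own number. The block there gives R106W and T158M a common effect of number, although 1 of 4 of their pairs lay over 0.1.

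Leaving out 1 library at a time gave 21 to 374 genes for R106W and 11 to 46 for T158M in excitatory nuclei, 1 to 174 between them, and in inhibitory nuclei 75 to 781, 9 to 69 and 0 to 2. It gave 9182 to 9667 between cell classes in WT, and 5 to 15 and 0 to 2 for the R106W and T158M effects between classes. In R106W heterozygotes it gave 1 to 4, 19 to 43 and 38 to 85, and in T158M heterozygotes 0 to 7, 0 to 5 and 13 to 52. In cortex it gave 7 to 222 (whole-cell), 37 to 1134 (nuclear) and 7 to 3837 (GRO-seq), and 1 to 119 (nuclear against GRO-seq), 0 to 23 (whole-cell against nuclear) and 1 to 17 (whole-cell against GRO-seq).

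The long-gene shift kept its direction, and its side of the threshold in camera with the preset correlation, with RLE size factors, no filter, replicate blocks, the 8 libraries alone, 1 cortex fit and a limit of 200 kb; Spearman's rho, given without a test, had the same direction. With an estimated correlation none of the 5 called shifts kept its call (adjusted p from 0.521 to 0.875). On leaving out 1 library it ran from −0.165 to −0.0643 (R106W) and −0.124 to −0.0209 (T158M) in excitatory nuclei, from −0.0945 to −0.0091 and −0.0763 to 0.0043 in inhibitory nuclei, from −0.0236 to 0.147 and −0.0751 to 0.0377 in R106W and T158M heterozygotes, and from 0.0167 to 0.107, −0.0716 to 0.139 and −0.224 to −0.0568 in whole-cell RNA, nuclear RNA and GRO-seq. It reversed without inhibitory WT replicate 4 (0.0043), without WT nuclei replicate 1 of R106W heterozygotes (−0.0236), without mutant replicate 1 or WT nuclei replicate 2 of T158M heterozygotes (0.0377, 0.0368) and without nuclear R106W replicate 2 or WT replicate 2 (−0.0025, −0.0716).

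Of 76 list calls over the 13 comparisons for which genes were named by rule, 0 passed in camera with an estimated correlation and 1 in fry, which called sodium and calcium channels for R106W in excitatory nuclei. In the other 8 comparisons 5 calls passed with an estimated correlation: 4 in inhibitory against excitatory WT nuclei, and immediate early genes between the alleles in inhibitory nuclei (0.048). Blocked by number, R106W heterozygotes lost the call of neuropeptides (0.051) and gained GABA receptors (0.015), T158M heterozygotes gained immediate early genes (0.027), glutamate receptors (0.025) and GABA receptors (0.017), and in male excitatory nuclei the block changed no list call for R106W (8) or T158M (6). Of 159 values for single named genes, DESeq2 ended 0 calls, no filter 1 and RLE size factors 2. With a block 118 stayed called and 15 did not, with the 8 libraries alone 49 did and 36 did not, and on leaving out 1 library 561 did and 523 did not. No named gene changed direction.

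Over genes with at least 20 counts in a pair, replicates differed on average by at least 3.99 times the variance of random sampling. Replicates thus varied beyond counting error, but this average does not show whether depth limited genes with few counts. In simulated data, 38.8% of genes changed 1.5-fold were called in nuclear RNA, and in female nuclei 62.7% where animals did not differ. With simulated differences between animals and no block, as fitted here, 0 of 67 genes changed 1.5-fold and 35.8% of those changed 2-fold were called; with the animal as a block it was 55.2% and 74.6%, and false calls made up 10.06% of the calls.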

Other observations

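All of the values below were chosen after they were seen, and none was planned as a test. Mecp2 stood at 94.6 to 112.8 CPM in male sorted nuclei, so its level does not tell WT from missense libraries. Fgfbp3, beside Btaf1 on chromosome 19, had an adjusted p of 0.169 in whole-cell and 0.212 in nuclear RNA. Ide stood at 87.5 CPM in WT and mutant nuclei of R106W heterozygote replicate 1, and at 133 and 136 in those of replicate 2. In T158M heterozygotes it stood at 93.3 and 97.1 in replicate 1 and at 56.2 and 59.0 in replicate 2.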
